A study of Mus musculus with 6 samples.

How the data were processed

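RNA from isolated islets of 3 Ucn3 null and 3 wild-type male mice was made into libraries with an Illumina TruSeq kit, per the labels' protocols. The labels call the material islets of mixed cell type, while the extraction protocol mentions a cell sort; islets are treated here as whole. The animals were littermates of both genotypes, but no label ties a null to a wild-type animal, so no pairing or block was used. Each library is 1 animal.

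The deposited table holds RPKM values made by the authors, 1 row per RefSeq transcript with a gene symbol. The submitters' processing notes name STAR, bedtools and DESeq, without roles or versions, and the mouse build mm9. How reads shared between transcripts or gene copies were counted, and whether strand was used, is not given in the sources used here. Which reads the depth term of RPKM counts is likewise not stated. Of 28129 rows, 117 had no values and 1 had text in a value cell; the other 28011 rows cover 21813 gene symbols. No row was at 0 in all libraries. Among 1507 genes with several transcripts above 5 RPKM, 52.5% had transcripts with proportional values within 0.1 percent, so transcripts of a gene often carry the same reads. For each symbol the transcript with the highest mean RPKM was kept. Genes averaging at least 1 RPKM over the 6 libraries were tested. Both of these choices were made after the table was opened and before any test was run.

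RPKM values are not counts, so the count model written in the plan was replaced by the fallback written there with it. Values were transformed to log2(RPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, group as the only term and eBayes with a mean trend, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are null minus wild type on the log2(RPKM + 1) scale and understate the change of low genes; ratios given in the text are of mean RPKM. Under the mean trend the standard error of Ins2 was 0.65. Gene lists, cell type markers, the main tests and the rule for named genes were fixed before the data were examined. Other tests, named below, were chosen after results were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over 23 of 26 lists. Camera compares the members of a list with the other tested genes, so a list can pass while its own mean is near 0. With the estimated correlation 0 lists passed and with fry 1 list, the delta cell markers; fry in its mixed form called 2.

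The rule named the CRF family and islet hormone genes, and up to 4 members of each list with the smallest p. It also named genes past the threshold with a mean log2 value above 1 and no overlap between groups. Up to 5 further genes in each direction, under the same level and no-overlap conditions, were given as values that did not pass. The level in this rule was planned for CPM and was applied to log2(RPKM + 1). Casr, Frzb, Akr1c12, Akr1c13, Tubal3, Marcksl1 and Amy2a5 fall outside it and were chosen after their values were seen. The list name Ffar4 was matched to the table's older symbol O3far1. The value of 1 member of the delta cell list is not reported here.

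Low RPKM values times transcript length fall on steps that stand for single reads, and these steps gave the depth of each library. Lengths came from GENCODE M21, matched for 97.5% of transcript rows. Between 77.8% and 79.6% of low values were whole within 0.1 read, so reads per gene are estimates. The reference is of another build than the table, so it was used for names, transcript lengths and which genes neighbour each other, and no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

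The fit was tested on simulated data for this comparison, with 200 of 12652 genes changed. With each gene's own SD, 71.6% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 22 of 188 calls, 11.7%, were false, more than the nominal rate. With SDs moderated by limma the shares were 64.2%, 98.5% and 98.5%, and 6 of 180 calls, 3.3%, were false. The second simulation was added after the first was seen. It drew noise from the SDs that the tested model itself estimates, so its low share of false calls is not an independent check. Both drew genes independently, without variation shared across the genes of a library, so recovery in the real data may be lower. Benjamini-Hochberg adjustment is also stricter where few genes differ than where 200 do. The shares therefore do not give the recovery to expect in the real comparison. There Hhex, with a wild type to null ratio of 1.95, had a limma adjusted p of 0.067. Camera called a simulated list of 20 genes raised 1.5-fold and 0 of 20 random lists. The simulated genes varied independently, while real lists had estimated correlations up to 0.873 for acinar markers and 0.709 for oxidative phosphorylation among those called. The simulation therefore does not test the preset correlation on lists whose members vary together.

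Alternatives covered the pseudocount, filters on low values, limma-voom on estimated reads, the acinar mean as a covariate and each library left out. Those chosen after seeing the data were scaling of RPKM by median ratio, upper quartile or equal totals, leaving out the 20 highest genes or the acinar list before scaling, another filter, no mean trend, correction for transcript length, every transcript row, and a window of 1 Mb around Ucn3.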

Results

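Islets were collected from 3 male Ucn3 null mice and 3 male wild-type littermates, all 3 months old, and the RNA of each animal was sequenced as a separate library. Urocortin 3, the product of Ucn3, is a peptide of the corticotropin-releasing factor (CRF) family that mature beta cells release together with insulin. The table gives RPKM, the density of reads on each RefSeq transcript scaled for its length and for the depth of the library. The steps between low values put the depth at 42660000, 48210000 and 48530000 reads for wild type replicates 1 to 3 and at 51970000, 48130000 and 46570000 reads for Ucn3 null replicates 1 to 3. No library repeated the values of another, and the correlation across genes between pairs of libraries lay between 0.955 and 0.989.

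The first question was whether the targeted gene was lost. Ucn3 fell from 149 ± 11.6 RPKM (SD, n = 3) in wild type to 1.68 ± 0.10 RPKM (SD, n = 3) in null islets, a ratio of 89.0. The wild-type libraries held 136, 157 and 155 RPKM and the null libraries 1.61, 1.63 and 1.80 RPKM, so all 6 libraries matched their labels. The log2 fold change was -5.81 (SE 0.08, limma adjusted p = 6.6e-08). The values in the null libraries correspond to about 124, 116 and 124 reads, against 8588, 11204 and 11120 reads in wild type. The other tested member of the CRF family was the receptor Crhr1, at 2.03 ± 0.39 RPKM in wild type and 1.78 ± 0.34 RPKM in null islets (SD, n = 3 each), a difference within the spread between animals. Ucn, Ucn2, Crhr2 and Crhbp averaged under 1 RPKM and were not tested. Crhr2, the preferred receptor of urocortin 3, held 0.49 ± 0.10 RPKM in wild type and 0.30 ± 0.07 RPKM in null islets (SD, n = 3 each), which is about 31 to 76 reads per library.

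The main comparison asked which other transcripts differ between null and wild-type islets. Of 12652 genes tested, 2 passed an adjusted p of 0.05 in limma, and both were lower in null islets: Ucn3 itself and Marcksl1-ps4, a pseudogene that lies beside Ucn3 on chromosome 13. Marcksl1-ps4 fell from 3.65 ± 0.40 to 0.49 ± 0.16 RPKM (SD, n = 3 each; log2 fold change -1.65, SE 0.11, limma adjusted p = 0.0052). Its values are uncertain because its reads can be shared with the parent gene Marcksl1, which was at 3.77 ± 1.19 RPKM in wild type and 2.38 ± 0.12 RPKM in null islets (SD, n = 3 each). No gene passed as higher. At an unadjusted p under 0.05 limma counted 1184 genes, 185 of them higher and 999 lower. Independent genes without any difference would give 633, and a grouping of the same libraries that mixes the genotypes gave 1281. That grouping set wild type replicate 1 and Ucn3 null replicates 1 and 2 against the rest. It also split the libraries by acinar marker mean, 6.71, 8.48 and 7.79 against 3.67, 5.52 and 6.45. The 1281 genes are therefore not what a grouping without any difference would give. Between null and wild-type libraries the values did not overlap for 1917 genes or 15.2%, where chance gives 10%. Without filtering low values 4 genes passed, 1 of them higher. Limma-voom on estimated reads called 1 gene, but Marcksl1-ps4 has no length here and was not in that fit. With the acinar mean as a covariate 1 gene passed, and Marcksl1-ps4 did not (log2 difference -1.67, SE 0.17, adjusted p = 0.22). Without wild type replicate 2 or wild type replicate 3, 1 gene passed as higher. The number of genes changed was 5 without Ucn3 null replicate 1 and 1 without Ucn3 null replicate 2, when Marcksl1-ps4 missed the threshold (log2 difference -1.60, SE 0.13, adjusted p = 0.055).

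Among the genes with the smallest p that did not pass, Hhex, a transcription factor needed for delta cell identity, was at 8.20 ± 0.42 RPKM in wild type and 4.20 ± 0.53 RPKM in null islets (SD, n = 3 each; limma adjusted p = 0.067). Spock3 was at 1.93 ± 0.10 and 0.74 ± 0.11 RPKM, Mest at 3.05 ± 0.16 and 1.62 ± 0.16 RPKM, Tmsb10, which encodes an actin-binding thymosin, at 16.8 ± 0.84 and 11.3 ± 0.61 RPKM, and Ehf at 5.86 ± 0.25 and 3.17 ± 0.53 RPKM in wild type and null islets (SD, n = 3 each). Their limma adjusted p ran from 0.12 to 0.16. In the other direction, Akr1c19 was at 20.1 ± 0.93 RPKM in wild type and 38.6 ± 4.59 RPKM in null islets (SD, n = 3 each; limma adjusted p = 0.067). Tmem179, Tmed6, Sdk2 and Prom1 followed with log2 differences of 0.43, 0.39, 0.44 and 0.67, each with an adjusted p of 0.49. For all of these genes, the 3 null libraries lay on one side of the 3 wild-type libraries. The rule that named them required this, so it is not a further result.

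Of the 8 islet hormone genes, none passed over all genes. Sst, which encodes somatostatin, the hormone of delta cells, was at 2038 ± 329 RPKM in wild type and 831 ± 197 RPKM in null islets (SD, n = 3 each), a wild type to null ratio of 2.45 (log2 difference -1.31, SE 0.21, limma adjusted p = 0.34). Wild-type libraries held 1676, 2117 and 2320 RPKM of Sst and null libraries 643, 816 and 1035 RPKM. Adjusted over the list alone, 1 of the 8 hormone genes passed, and it was Sst. Ins1 was at 32298 ± 3493 and 32173 ± 3550 RPKM, Ins2 at 217124 ± 15106 and 194907 ± 9322 RPKM, Iapp at 17052 ± 1746 and 15739 ± 817 RPKM, and Gcg at 8376 ± 459 and 7886 ± 2112 RPKM in wild type and null islets (SD, n = 3 each), with overlapping groups for each. Ins2 overlapped narrowly, at 202206 RPKM in wild type replicate 1 and 202333 RPKM in Ucn3 null replicate 2. The mean trend gave Ins2, Ins1 and Iapp standard errors of 0.65, 0.35 and 0.27. For these abundant genes the lack of a call says little about whether they changed. Ppy, Pyy and Ghrl also overlapped between the groups, with log2 differences of -0.28, -0.26 and -0.46 (with 1 library left out, -0.714 to 0.116, -0.544 to -0.001 and -0.642 to -0.174). The hormone list as a group did not pass (camera adjusted p = 0.24), but it passed as lower where the acinar list was left out before scaling (mean -0.249, camera adjusted p = 0.021). With 1 library left out its mean difference ranged from -0.499 to -0.162.

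Delta cell markers were lower as a group. The list mean of log2(RPKM + 1) was 4.48 ± 0.06 in wild type and 4.03 ± 0.09 in null islets (SD, n = 3 each), a difference of -0.46 over 8 tested members, with every null library below every wild-type library. The preset camera test gave an adjusted p of 0.00075 over 23 lists. The call was lost with an estimated correlation (adjusted p = 0.60 with an estimated correlation). The fry test, which asks whether the members move on balance in 1 direction and does not compare them with other genes, gave an adjusted p of 0.025. No member passed over all genes. Adjusted over the list alone, 6 of 8 members passed, 5 of them lower: Hhex, Spock3, Rbp4, Sst and O3far1. Rbp4, a retinol carrier, stood at 67.6 ± 7.93 and 39.0 ± 4.48 RPKM and O3far1, a receptor for long-chain fatty acids also called Ffar4, at 2.83 ± 0.23 and 2.11 ± 0.28 RPKM in wild type and null islets (SD, n = 3 each). The sixth, Casr, the calcium-sensing receptor, was higher, at 10.3 ± 0.32 and 12.5 ± 1.41 RPKM. Frzb overlapped between groups, with a log2 difference of -0.01. Markers of other cell types moved in the same libraries. Ductal markers were lower too, with a mean difference of -0.30 (Krt19 -1.31), and acinar markers were higher by 2.27. Unlike the delta list, the ductal and acinar lists had library means that overlapped between the groups.

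**Figure D1:**
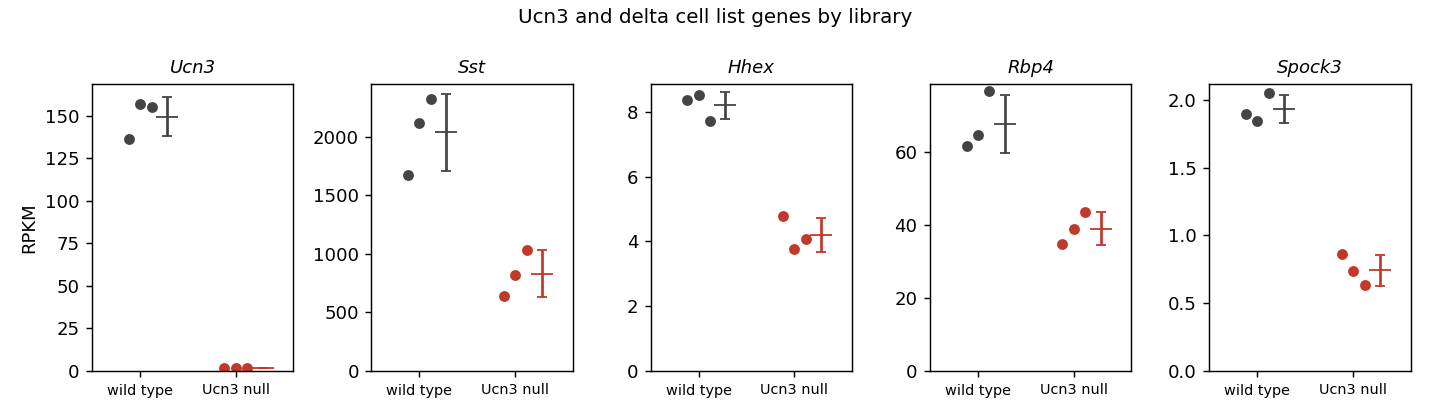
RPKM (vertical axes, each from 0) of Ucn3, Sst, Hhex, Rbp4 and Spock3 in the 3 wild-type and 3 Ucn3 null libraries; points are single animals, and bars beside them give the mean and SD of 3. Every null library lies below every wild-type library for each gene; Sst ranges from 1676 to 2320 RPKM in wild type and from 643 to 1035 RPKM in null islets.

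Beta cell identity genes showed no shift as a group. The mean difference over 26 tested genes was 0.02 on the log2 scale, with 13 members positive and 13 negative, none past the threshold over all genes or over the list alone, and a camera adjusted p of 0.070. The list passed as higher without wild type replicate 2, wild type replicate 3 or Ucn3 null replicate 3 (camera adjusted p = 0.022, 0.037 and 0.0062). Its mean differences were then 0.017, 0.052 and 0.018, against medians of all genes of -0.05, -0.025 and -0.068 in the same fits. Camera compares the list with other genes, so these calls do not show that beta cell genes rose. Nkx6-1, a transcription factor of mature beta cells, was at 58.0 ± 2.96 and 70.5 ± 6.10 RPKM, Glp1r, the receptor of glucagon-like peptide 1, at 88.9 ± 12.1 and 117 ± 15.5 RPKM, Abcc8, a subunit of the ATP-sensitive potassium channel, at 143 ± 8.58 and 165 ± 12.6 RPKM, and Pcsk1, a prohormone convertase, at 107 ± 6.19 and 94.2 ± 6.95 RPKM in wild type and null islets (SD, n = 3 each). Genes of immature or dedifferentiated beta cells did not pass (14 tested, mean difference -0.12, camera adjusted p = 0.26), but passed as lower without wild type replicate 3 (camera adjusted p = 0.037) and with the acinar list left out before scaling (camera adjusted p = 0.048). Within that list Aldh1a3, an enzyme of retinoic acid synthesis, was at 1.38 ± 0.11 RPKM in wild type and 3.73 ± 2.08 RPKM in null islets (SD, n = 3 each; limma adjusted p = 0.49), and Sox9 was at 1.46 ± 0.46 and 0.71 ± 0.45 RPKM. Alpha cell markers, 11 tested, had a mean difference of 0.04 (camera adjusted p = 0.25) and passed as higher without Ucn3 null replicate 1 (0.137, camera adjusted p = 0.026), with Peg3 and Tmem27 at log2 differences of 0.42 and -0.20. The 3 tested PP cell markers were too few for a list test, with a mean difference of -0.18.

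Acinar markers, which belong to the exocrine tissue around islets, differed widely between single libraries. The mean log2(RPKM + 1) of 34 tested genes was 6.71, 3.67 and 5.52 in wild type replicates 1 to 3 and 8.48, 7.79 and 6.45 in Ucn3 null replicates 1 to 3. The group difference was 2.27, from 1.456 to 2.972 with 1 library left out, and all 34 members were positive, but wild type replicate 1 lay above Ucn3 null replicate 3 and the exact two-sided permutation p was 0.2. The preset camera test gave an adjusted p of 7.9e-33 (adjusted p = 0.70 with an estimated correlation). No member passed over all genes, and 33 passed adjusted over the list alone. Reg1 was at 48.1 ± 43.2 and 236 ± 117 RPKM, Ctrc at 1.16 ± 0.94 and 5.53 ± 3.02 RPKM, and Rbpjl at 0.47 ± 0.34 and 2.07 ± 1.0 RPKM in wild type and null islets (SD, n = 3 each). Ductal markers moved the other way, with a mean difference of -0.30 over 14 tested genes, from -0.451 to -0.19 with 1 library left out, and 13 of them negative (camera adjusted p = 0.00014, adjusted p = 0.71 with an estimated correlation). The groups overlapped, with a ductal list mean of 4.24 in Ucn3 null replicate 1 and 4 in wild type replicate 3. Adjusted over the list alone 3 ductal markers passed, all lower: Epcam at 44.2 ± 3.09 and 34.9 ± 1.03 RPKM, Krt19 at 18.2 ± 4.76 and 7.41 ± 4.86 RPKM, and Spp1 at 77.6 ± 15.7 and 39.7 ± 18.8 RPKM. Tff2, at 9.29 ± 5.16 and 30.4 ± 17.9 RPKM, was the 1 ductal list member with a positive difference.

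**Figure D2:**
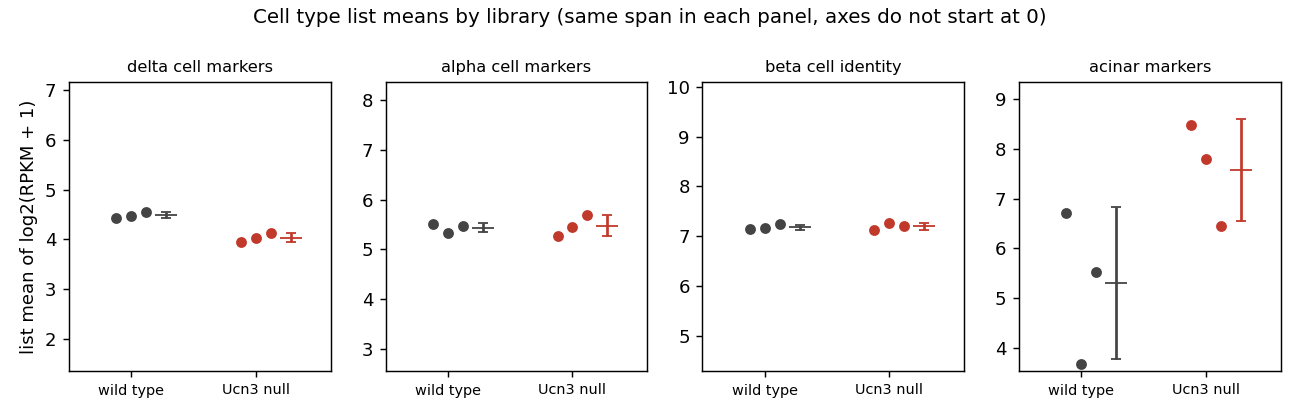
Mean log2(RPKM + 1) of the delta, alpha, beta and acinar lists in each library (vertical axes cover the same span in each panel and do not start at 0); points are single animals and bars give the mean and SD of 3. The delta list separates the groups (4.48 and 4.03), while the acinar list spreads from 3.67 to 8.48 and its groups overlap.

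Markers of the other cell types did not pass as lists with the settings of the main comparison, though several did under alternatives. Endothelial markers had a mean difference of 0.03 over 14 genes (camera adjusted p = 0.070; Flt1 0.15), stellate and fibroblast markers -0.07 over 7 genes (0.88; Dcn -0.60), macrophage and dendritic markers -0.27 over 16 genes (0.070; Cd14 -0.65, Tyrobp -0.19), B and T cell markers -0.18 over 6 genes (0.73; Cd79a -0.26) and red blood cell markers -0.65 over 6 genes (0.30; Hbb-b1 -0.83, from -1.613 to -0.412 with 1 library left out). The macrophage and dendritic list passed as lower in 7 alternatives: no filter, limma-voom, without wild type replicate 3 (-0.427, camera adjusted p = 2.5e-05), without Ucn3 null replicate 2 (-0.374, camera adjusted p = 0.00058), and scaling by median ratio, equal totals or equal totals without the acinar list. Red blood cell markers passed as lower without wild type replicate 3 (-1.333, camera adjusted p = 5.8e-05), without Ucn3 null replicate 2 (-1.159, camera adjusted p = 0.0030) and with the acinar list left out before scaling (-0.572, camera adjusted p = 0.048). The estimated correlation of the red blood cell list was 0.994 with all libraries, against the preset of 0.01. Its members therefore act almost as 1 measurement, and these p-values are too small. Endothelial markers passed as higher without wild type replicate 1 (0.086, camera adjusted p = 0.0056) or Ucn3 null replicate 2 (0.059, camera adjusted p = 0.013). B and T cell markers passed as lower without wild type replicate 3 (-0.443, camera adjusted p = 0.013), and stellate and fibroblast markers with the acinar covariate (-0.327, camera adjusted p = 0.033). The estimated correlation with all libraries was 0.86 for the B and T cell list and 0.526 for the stellate and fibroblast list. The 3 tested Schwann and neuronal markers were given no list test, and Th among them had a log2 difference of 0.15. Hbb-b1 cannot be told from its copy Hbb-b2, which has the same value in every library.

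Functional lists moved little. Oxidative phosphorylation genes had a mean difference of -0.13, with 31 of 32 members negative (camera adjusted p = 0.00014, adjusted p = 0.82 with an estimated correlation), Ndufb5 at 29.1 ± 0.32 and 24.6 ± 0.82 RPKM and Cox6c at 68.5 ± 3.69 and 54.4 ± 5.99 RPKM in wild type and null islets (SD, n = 3 each). With the acinar mean as a covariate the mean difference was 0.015 and did not pass. Secretory granule and exocytosis genes had a mean difference of 0.06 over 29 genes (camera adjusted p = 0.0049, adjusted p = 0.82 with an estimated correlation; Vgf 0.53, from 0.298 to 0.809 with 1 library left out, Unc13a 0.22). Somatostatin and islet receptor genes had 0.06 over 13 genes, 11 of them positive (camera adjusted p = 0.046, adjusted p = 0.71 with an estimated correlation). The granule list did not pass without wild type replicate 1 (camera adjusted p = 0.12), and the receptor list did not pass without wild type replicate 1, Ucn3 null replicate 1 or Ucn3 null replicate 2 (camera adjusted p = 0.14, 0.060 and 0.18). The receptor list was also lost without a filter (camera adjusted p = 0.079), with the acinar covariate (0.27), with median-ratio (0.082) or upper-quartile factors (0.072), with the acinar list left out before scaling (0.054) and with values corrected for length (0.12). It kept its call in 10 of 19 alternatives. No member of these 3 lists passed over all genes or adjusted over the list alone. In each of these lists the library means overlapped between the groups. The acinar mean differed by 2.27 between the same groups.

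The remaining lists did not pass with the settings of the main comparison. Mean differences were -0.02 for the unfolded protein response (25 genes; Sel1l 0.21, Hsp90b1 -0.22), 0.02 for immediate early and dissociation stress genes (25 genes; Hspb1 -0.46), -0.06 for hypoxia and glycolysis (21 genes; Tpi1 -0.15), -0.11 for the cell cycle (11 genes; Mcm6 -0.27), 0.07 for the cAMP response (19 genes; Pde10a 0.45), 0.01 for cholesterol and fatty acid synthesis (24 genes; Sc5d -0.21) and -0.12 for the interferon response (13 genes; B2m -0.49). Their camera adjusted p ran from 0.18 to 0.89, and 0 members passed adjusted over each list alone. Several of them passed under alternatives. The unfolded protein response passed as higher with the acinar mean as a covariate (0.137, camera adjusted p = 0.00028) and without wild type replicate 2 (0.055, camera adjusted p = 0.019). Immediate early genes passed in opposite directions, as higher without wild type replicate 1 (0.333, camera adjusted p = 3.9e-06), wild type replicate 2 (0.076, camera adjusted p = 0.011) or Ucn3 null replicate 2 (0.142, camera adjusted p = 0.018), and as lower without wild type replicate 3 (-0.352, camera adjusted p = 2.8e-06). The estimated correlation of this list was 0.845 with all libraries, against the preset of 0.01, so these p-values are too small. Without wild type replicate 1 the cell cycle list passed as lower (-0.146, camera adjusted p = 0.040) and the cAMP list as higher (0.245, camera adjusted p = 0.0057). The interferon list passed as lower without wild type replicate 3 (-0.175, camera adjusted p = 0.040). Cholesterol and fatty acid genes passed as higher without wild type replicate 2 (0.026, camera adjusted p = 0.012), Ucn3 null replicate 1 (0.083, camera adjusted p = 0.0074) or Ucn3 null replicate 3 (0.015, camera adjusted p = 0.0096).

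A further question was whether genes next to the targeted locus differ more often than others, since a targeted allele can carry flanking sequence from the strain it was made in. Within 10 Mb of Ucn3 on chromosome 13, leaving out Ucn3, 1 of 31 tested genes passed, Marcksl1-ps4, against 0 of 12573 elsewhere. The planned test (two-sided Fisher's exact p = 0.0025) rests on this 1 gene, whose reads are uncertain, and is not read as a difference between the window and other genes. At an unadjusted p under 0.05, 6 of 31 genes within 10 Mb differed, 19.4%, against 9.31% elsewhere (odds ratio 2.34, 95% interval 0.78 to 5.85, Fisher's exact p = 0.064), 6 of 16 within 5 Mb (Fisher's exact p = 0.0023) and 16 of 104 within 20 Mb, 15.4% against 9.29% (Fisher's exact p = 0.041). The windows are nested, and the 6 genes within 5 Mb are the same as those within 10 Mb. The fixed list of neighbours, 22 genes tested, had no common direction (camera adjusted p = 0.95, mean difference -0.035). The mixed form of fry, which asks whether members change in either direction, gave an adjusted p of 3.0e-06. Adjusted over the list alone 4 of 22 passed, Akr1c19 and Net1 as higher and Akr1c14 and Adarb2 as lower. Akr1c14 was at 17.5 ± 1.58 and 10.9 ± 1.65 RPKM, Net1 at 2.56 ± 0.15 and 3.54 ± 0.48 RPKM and Adarb2 at 9.84 ± 0.57 and 7.78 ± 0.22 RPKM in wild type and null islets (SD, n = 3 each). Akr1c12, which did not pass, was at 29.9 ± 1.63 and 25.3 ± 1.30 RPKM. The Akr1c genes encode closely related aldo-keto reductases and their values are uncertain where reads are shared between them. Tubal3, too low for the main test, held 2, 1 and 0 estimated reads in wild type replicates 1 to 3 and 49, 49 and 45 in Ucn3 null replicates 1 to 3. It passed where low values were kept (log2 fold change 0.38, limma adjusted p = 0.0065).

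The last comparison set the overall profile against genotype. The test of the first component against the acinar mean was chosen after the scores were seen. The first principal component of the 500 most variable genes carried 54.2% of the variance. Wild type replicates 1 to 3 scored -0.51, 22.1 and 8.55, and Ucn3 null replicates 1 to 3 scored -17.9, -11.0 and -1.19. The groups did not overlap and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. The scores also followed the acinar mean of each library (Spearman correlation -0.943 over 6 libraries, exact permutation p = 0.017), and the acinar genes are among those the component was computed from. With all tested genes it was 0.2, and the scores followed the acinar mean in order (Spearman correlation -1, exact permutation p = 0.0028). With the acinar list left out the first component carried 36.9%, with an exact permutation p of 0.1, and it followed the acinar mean as closely (Spearman correlation -0.943, exact permutation p = 0.017). Genotype and acinar content are not separated by this component. The second component carried 18.6% and gave an exact permutation p of 0.6.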

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

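Ucn3 kept its direction and its call in every alternative run, with a log2 fold change between -5.88 and -5.77 when a library was left out. The mean of the delta cell list stayed negative and past the preset camera threshold in all 19 alternatives, from -0.569 to -0.333 with adjusted p from 1.3e-05 to 0.0096; the estimated correlation is the exception. Over the named genes 1203 of the alternative values kept direction and side of the threshold, 32 changed sign, 4 gained a call and 2 lost one; over single lists 361 kept both, 33 changed sign, 33 gained a call and 12 lost one, and 3 of the gained and 1 of the lost also changed sign. The planned count models with other normalizations, and DESeq2 and edgeR, were not run because the values are RPKM. Scalings of RPKM were chosen after seeing the data in their place, as were the other added alternatives named with the processing; no scaling moved the median of all genes by over 0.1. No paired analysis was possible because no label ties a null to a wild-type animal.

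The number of genes changed was 4 without a filter on low values, 1 with limma-voom on estimated reads, 1 with the acinar mean as a covariate, 4 with the 20 highest genes left out and 1 with values corrected for length. Genes higher numbered 1 without a filter and 1 with the 20 highest genes left out. Genes lower numbered 1 with limma-voom, 1 with the acinar covariate and 1 with values corrected for length. Beside Ucn3 and Marcksl1-ps4, the added calls were Mir1983 and Tubal3 without a filter, Akr1c19 and Hhex with the 20 highest genes left out, Cttnbp2, Ehf and Hhex without Ucn3 null replicate 1, Gm10421 without Ucn3 null replicate 3, Mir153 without wild type replicate 2 and Mir1930 without wild type replicate 3; Mir1983, Mir153, Mir1930, Gm10421, Tubal3 and Cttnbp2 were named after their values were seen. Marcksl1-ps4 has no length here and so was not in the limma-voom and length-corrected fits; with the acinar covariate its log2 difference was -1.672 (SE 0.174) against -1.646 (SE 0.111) without, and its adjusted p was 0.22. The standard error grew and the fit has fewer degrees of freedom, while the difference did not shrink. With 1 library left out, genes changed ranged from 1 to 5, higher from 0 to 1 and lower from 1 to 5. The lists past the threshold numbered 0 with an estimated correlation, 1 with fry, and 7 to 13 with 1 library left out, more than the 6 with all libraries. The cause was not tested. For genes near Ucn3 the Fisher's exact p was 0.0637 with unadjusted calls within 10 Mb. The first principal component gave no other call.

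With the acinar covariate the sign turned for Ins1 (0.133), Iapp (0.062), Gcg (0.101), Ppy (0.069), Pyy (0.206), Ghrl (0.236), Peg3 (-0.073), Frzb (0.079), Flt1 (0), Amy2a5 (-0.295) and Akr1c13 (0.025), none of them past the threshold. The list means that turned with it were endothelial (-0.041), unfolded protein response (0.137, camera adjusted p = 0.00028), immediate early (-0.137), hypoxia (0.005), cell cycle (0.008), cAMP (-0.142) and oxidative phosphorylation (0.015).

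Ins1 turned to 0.047 with median-ratio factors, 0.031 with upper-quartile factors, 0.032 with equal totals, 0.084 with the acinar list left out and 0.059 with length-corrected values. Frzb turned to 0.045, 0.029, 0.031, 0.082 and 0.017 under the same settings, and the unfolded protein response list to 0.032, 0.017, 0.019, 0.069 and 0.021. The list of genes near Ucn3 turned to 0.012 with median-ratio factors and 0.045 with the acinar list left out, where the hypoxia list was at 0.024. With 1 library left out, values that changed sign ranged from -0.098 to 0.063 for Ins1, -0.314 to 0.079 for Gcg, -0.714 to 0.116 for Ppy, -0.061 to 0.031 for Frzb and -0.071 to 0.327 for Th. List means that changed sign ranged from -0.011 to 0.061 for beta cell identity, -0.069 to 0.137 for alpha cells, -0.017 to 0.086 for endothelial, -0.21 to 0.057 for stellate, -0.443 to 0.064 for B and T cells, -0.113 to 0.055 for the unfolded protein response, -0.352 to 0.333 for immediate early, -0.038 to 0.245 for cAMP and -0.071 to 0.083 for cholesterol and fatty acid synthesis. List means that kept their sign but moved by more than 1.5 times ranged from 1.456 to 2.972 for acinar, -0.451 to -0.19 for ductal, -0.499 to -0.162 for hormones and -0.172 to -0.04 for immature beta cells. They ranged from -0.427 to -0.145 for macrophages, -1.333 to -0.258 for red blood cells, -0.094 to -0.025 for hypoxia and -0.146 to -0.059 for the cell cycle. The others were -0.175 to -0.074 for interferon, 0.027 to 0.113 for secretory granules, 0.028 to 0.095 for receptors and -0.06 to -0.003 for genes near Ucn3. Named genes that kept their sign but moved by as much ranged from -0.544 to -0.001 for Pyy, -0.642 to -0.174 for Ghrl, -0.2 to -0.065 for Iapp, -0.216 to -0.016 for Crhr1 and 0.202 to 0.583 for Peg3. Among markers they ranged from -1.613 to -0.412 for Hbb-b1, -0.99 to -0.342 for Dcn, -0.529 to -0.061 for Cd79a, 0.088 to 0.204 for Flt1, 1.774 to 3.449 for Reg1 and 1.531 to 3.47 for Amy2a5. The others were 0.298 to 0.809 for Vgf, -0.839 to -0.199 for Hspb1, -0.639 to -0.302 for B2m, -0.308 to -0.103 for Akr1c13 and -0.664 to -0.294 for Marcksl1. The values that changed sign lie near 0 or vary widely between libraries; the cause was not tested.

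Depth limits the lowest genes: Crhr2 rests on 31 to 76 and Tubal3 on 0 to 49 estimated reads per library, and folds of such genes on the log2(RPKM + 1) scale are too small.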

Other observations

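The tests of acinar dilution, transcript length, acinar carry-over, shared Akr1c reads and the window of 1 Mb were chosen only after the results were seen. The planned main test used the window of 10 Mb, and the windows of 5 and 20 Mb were alternatives to it. The tables also hold a trend with transcript length that no list covers. Across 12430 genes the log2 difference between null and wild-type islets was correlated with transcript length (Spearman's rho 0.304 across genes, which are not independent replicates). Its median was -0.041 for 315 genes under 150 nucleotides, -0.145 for 299 genes of 150 to 600 and 0.018 for 1979 genes above 5000. After correction of each library for length, rho was 0.081.

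Delta cell markers were lower in null islets, with a list mean of -0.458, and ductal markers were lower in the same comparison, with a list mean of -0.304. Library means of the ductal list overlapped between the groups, while those of the delta list did not. Dilution of islet RNA by acinar RNA would lower alpha and beta cell genes alike, but 37 alpha and beta list members had a median of 0.005 (SD 0.15), which argues against it as the whole source. The length trend is argued against too, since the list mean was -0.418 with a camera adjusted p of 0.00101 after correction. Of the 10 splits of the 6 libraries, 1, the real one, gave a mean as large, and the highest other was 0.247; 10 splits are too few for a share under 0.05. Not every member fell: 6 of 8 had a negative difference, Casr was higher (log2 difference 0.24) and Frzb was at -0.01. Fewer delta cells and less transcript per delta cell both remain open as hypotheses for the loss of Ucn3, untested in whole islets. Counts of delta cells or RNA of sorted delta cells would separate these hypotheses. Neither was separated from differences between islet samples unrelated to genotype. The preset list call did not hold with an estimated correlation.

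Acinar markers were higher on average in null islets. A candidate explanation is exocrine tissue carried over with the islets: after group means were removed, the 34 acinar genes had a median pairwise correlation of 0.993, and abundant ones moved together, with Amy2a5 at 166 RPKM in wild type replicate 2 and 9407 RPKM in Ucn3 null replicate 1. Whether the carry-over is related to genotype cannot be told apart with 3 animals per group (exact permutation p = 0.2, where the smallest possible is 0.1). The labels' mention of a cell sort, which would remove such tissue, is not matched by these levels.

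Genes beside Ucn3 differed in both directions, and a flanking segment from another strain may be the source. The share of genes at an unadjusted p under 0.05 within 10 Mb did not pass (Fisher's exact p = 0.0637), although it did within 20 Mb (0.0412), 5 Mb (0.0023) and 1 Mb (0.00119). These windows are nested, and 5 of the 6 genes called within 5 Mb lie within 1 Mb. Those 5 are Marcksl1-ps4, Akr1c19, Akr1c14, Net1 and Akr1c12, all but Net1 with reads that may be shared. The p-values are therefore not separate evidence. On the fixed list of neighbours, Adarb2 also passed adjusted over the list alone, at 9.84 RPKM in wild type and 7.78 RPKM in null islets. Tubal3, too low for the main test, held 2, 1 and 0 estimated reads in wild type and 49, 49 and 45 in null islets. Shared reads were not examined for Adarb2 or Tubal3. No test here sets such a segment against an effect of the targeted allele on its neighbours. For the Akr1c genes, reads shared between these related genes remain a possible explanation, though sharing was not measured. Akr1c19 differed by 22.99 RPM (reads scaled to depth) while Akr1c14, Akr1c12 and Akr1c13 differed by -16.23, -5.81 and -4.86. The sum over 4 genes differed by -3.906, a size below the null SD of 10.5 but above the wild-type SD of 3.57, so it does not settle the question.

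Other groupings of the 6 libraries were also fitted. The real grouping called 2 genes, and the highest of the others called 6; 2 of the 10 splits called as many as the real one. In 1 direction the real grouping called 2 lower and the highest other 5, again 2 of 10 splits. The real grouping called 6 lists and the highest other 11, and all 10 splits called as many. With 10 splits no share under 0.05 can be reached. At an unadjusted p under 0.05 the real grouping reached 1184 genes and the highest other 1281, so 2 of the 10 splits reached as many. The 1281 came from wild type replicate 1 with Ucn3 null replicates 1 and 2 against the rest. This grouping also sets higher acinar means against lower ones. The 6 genes came from a single grouping, wild type replicates 1 and 2 with Ucn3 null replicate 2 against the rest, and the other 8 called 0 or 1. That single grouping also split the libraries by red blood cell marker mean. The means were 6.21, 6.28 and 5.92, against 4.21, 4.12 and 4.69 in the rest. Whether this gave the 6 calls was not tested.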
